A study of Mus musculus with 4 samples.

How the data were processed

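RNA was measured in mouse bone marrow leukaemic cells carrying the MLL-AF9 knock-in, a fusion of the Mll1 (Kmt2a) gene with a partner gene that drives acute myeloid leukaemia. Control cells had the MLL-AF9 allele alone, and Meis1f/f cells also carried floxed Meis1 alleles and the CreER transgene, a tamoxifen-activated recombinase. Cells of each genotype received vehicle or 1000 nM 4-hydroxytamoxifen (4-OHT) for 24 h. The medium held GM-CSF, IL-3, IL-6 and SCF at 10 ng/ml, and the serum content was 10% in the design text and 20% in the growth protocol. There were 4 libraries in 4 groups, 1 per group, each taken to its group from its label.

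Reads were aligned with Bowtie and the mm8 build is named, per the submitters' processing notes; versions, the annotation release, read length, strandedness and filters are not given in the sources used here. The deposited tables held 28107 transcript rows for 22072 symbols per library. The FPKM column was computed by the authors per kilobase of transcript and per M (mega) mapped fragments, per the file headers. The coverage column, a signal of mean read depth per base that is not scaled between libraries, was also made by the authors, per the file headers. The tool that made both columns is not named in the sources used here. Coordinates are given as deposited; whether they follow mm8 or a later build was not settled, and the sources do not say whether positions count from 0 or 1.

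Within each file coverage divided by FPKM was constant, so it gave the relative depth of the library. Coverage times length of low single-transcript genes longer than 500 bases (window of 20 to 70 bases) had a median of 45.3, 45.3, 44.8 and 44.8 bases in the control vehicle, control 4-OHT, Meis1f/f vehicle and Meis1f/f 4-OHT libraries, taken here as the value of 1 read. On that basis depth was estimated at 28.5, 22.2, 43.1 and 18.4 M mapped reads. The middle of the window lies near the medians, so the window itself may set them. The depths in reads, the estimated reads and the widths of the counting intervals are uncertain for that reason. The relative depth from coverage and FPKM does not rest on the window. For a transcript of 2 kb, 1 read was worth 0.0176, 0.0226, 0.0116 and 0.0272 FPKM. The values were not whole multiples of a step, so reads were not recovered and no count test was run. Ratios of FPKM of single genes carry 95% exact (Clopper-Pearson) binomial intervals from the estimated reads, which cover counting error only. They leave out variation between cultures and the splitting of reads between transcripts, and PCR copies are not independent molecules.

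Transcripts marked OK in all 4 libraries were used, a choice made after the files were seen; 394 rows had another status in at least 1 library. A symbol was represented by its row with the highest mean, and 10922 symbols reached 1 FPKM in at least 1 library, 2340 of them with more than 1 row. Differences are on the log2(FPKM + 1) scale, which understates differences of low genes. With 1 library per group there was no replicate check, no test and no p-value; a gene was counted as higher or lower at a log2 difference of at least 1 in size. Compared were 4-OHT with vehicle in each genotype, the Meis1f/f difference minus the control difference (the difference of the 4-OHT effects), and the genotypes under vehicle. A gene was counted as deletion-associated when its difference in Meis1f/f cells and the difference of the effects both reached 1 with the same sign. The comparison of the genotypes under 4-OHT was added after the data were seen.

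For 37 gene lists the median difference of the members was placed among 10000 random lists of the same size drawn from 10 bins of mean log2 value. A list was called apart at a percentile of at most 2.5 or at least 97.5. This describes these libraries; genes of a pathway vary together, which random lists do not imitate, and the order-statistic interval of a median covers the spread over members only. Of the lists, 2 had fewer than 5 members over the floor and received no percentile.

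The lists, size rule, floor, pseudocount and rule for named genes were fixed before the data were examined. That rule names Meis1, Hlf, Esr1 and Mll1; the 12 highest and 12 lowest deletion-associated genes by the difference in Meis1f/f cells (at least 5 FPKM in a Meis1f/f library); the 5 highest and 5 lowest for 4-OHT in control cells; the 10 highest and 10 lowest between genotypes under vehicle, both with the same 5 FPKM minimum in a library compared; and in each list up to 4 members with the largest difference of the effects in size. Small RNAs, unnamed gene models and pseudogene copies were left out of the rankings. Genes named outside that rule were chosen after their values were seen: Vegfa, Hif1a, Slc2a1, Pgk1, Hoxa9, Hoxa7, Cpa3, Prss34, Gata2, Gata1, Prtn3, F2r, H2-Aa, H2-Ab1, Itgax, Hba-a1, Perp, Phlda3, Zmat3, Cdkn2b, Csf2rb, Csf2rb2 and Osm.

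Alternatives were a pseudocount of 0.1 or 5, no floor or a floor of 5 FPKM, rescaling each library by median ratio or upper quartile, summing the rows of a symbol, unmatched random lists and the mean in place of the median. Chosen after the data were seen were transcripts of every status, removal of the trend with transcript length in 40 bins, random lists matched on length or on transcript GC content as well (5 by 5 bins; GENCODE M21 gave a GC content for 98.3% of genes), and the count of deletion-associated genes that also differed between the 4-OHT libraries.

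The functions were tested on simulated data: Poisson reads for 10581 genes at the estimated depths, with changes planted in the Meis1f/f 4-OHT library. For the 4-OHT effect in Meis1f/f cells, 0 of 50 genes changed 1.5-fold passed the size rule, as did 9 of 50 changed 2-fold, 47 of 50 changed 4-fold and 50 of 50 changed 8-fold. Of 10351 unchanged genes, 11 passed through counting noise alone. For the difference of the 4-OHT effects, 4 of 100 unchanged lists of 30 genes were called apart, and a list of 30 genes raised 1.41-fold was called apart. The unchanged lists were random draws, so a share near that of the rule was set in advance. It does not cover pathway lists, whose genes vary together. In the data 7 of 35 lists were called higher and 11 lower in the difference of the effects. Between genotypes the calls were 16 and 8 under vehicle and 17 and 9 under 4-OHT. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.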

Results

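Transcript levels were measured by RNA sequencing in MLL-AF9 leukaemic bone marrow cells of C57BL/6 mice. The design asks how 24 h of 4-OHT, which activates the CreER recombinase and is used to delete floxed alleles, altered expression in Meis1f/f cells compared with control cells. MEIS1 is a homeodomain transcription factor that works with HOXA proteins in MLL-rearranged leukaemia. There was 1 library for each of 4 groups: control vehicle, control 4-OHT, Meis1f/f vehicle and Meis1f/f 4-OHT. Estimated depth was 28.5, 22.2, 43.1 and 18.4 M mapped reads in that order. As said above, these depths in reads are uncertain because the window may set the value of 1 read, while the relative depth does not rest on it. Between 10051 and 10425 symbols reached 1 FPKM per library. No difference below has a replicate check. Per the labels the control cells carry no CreER, so recombinase activation and loss of Meis1 were not separated by this design. The sheet names place the Meis1f/f vehicle library in lane 1 and the other 3 libraries in lane 2.

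Meis1 (chromosome 11, 18780430 to 18918972; positions as deposited, on a build that was not settled) was lower in the Meis1f/f 4-OHT library than in the other 3. Its main transcript was at 11.6 FPKM in control vehicle, 12.1 in control 4-OHT, 11.8 in Meis1f/f vehicle and 7.38 in Meis1f/f 4-OHT cells. The ratio of 4-OHT to vehicle was 0.625 in Meis1f/f cells (95% exact counting interval 0.563 to 0.693) and 1.05 in control cells (0.958 to 1.14). Summed over its 2 transcript rows, Meis1 was at 13.8, 13.2, 15.5 and 8.08 FPKM in the same order. FPKM counts reads along the whole transcript, and the floxed part of Meis1 is not given in the sources used here, so this level is only a partial check of the label and does not measure intact transcript. Hlf, a PAR bZIP transcription factor that the study's title joins to MEIS1, was under 1 FPKM in every library. It was at 0.516, 0.531, 0.370 and 0.160 FPKM, and its ratio in Meis1f/f cells was 0.432 (0.247 to 0.749) against 1.03 (0.74 to 1.45) in control cells, from an estimated 16.7 reads in the Meis1f/f 4-OHT library. Mll1, which is read from the fused as well as the normal allele, was at 2.20, 1.85, 5.03 and 2.28 FPKM. Its transcript is 16439 bases long, and the Meis1f/f vehicle library, where it was highest, carried a trend towards higher values of long transcripts (given below). How much of the Mll1 difference goes with that trend was not tested. Esr1, the oestrogen receptor gene, was at 3.19, 2.95, 2.58 and 2.04 FPKM.

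Tgm2 and Thbs1 were among the genes lower with 4-OHT in Meis1f/f cells. Tgm2, tissue transglutaminase (chromosome 2, 157942140 to 157972128), was at 363 FPKM under vehicle and 8.98 under 4-OHT, 40.4-fold lower, with 56.1 and 38.2 FPKM in control cells. Thbs1, the matricellular protein thrombospondin 1 (chromosome 2, 117937657 to 117952869), was at 521 and 20.8 FPKM, 25.1-fold lower, with 362 and 427 FPKM in control cells. Samd5 was at 12.6 and 0.143 FPKM and Bpil2 at 11.7 and 0.559 FPKM. Hmox1, haem oxygenase 1, was at 188 and 32.7 FPKM, and Slc7a11, the cystine transporter subunit, was at 49.6 and 6.97 FPKM. Trib3, a target of ATF4, was at 32.5 and 5.68 FPKM. Also lower were Il4 (14.3 and 1.5 FPKM), Il13 (16.1 and 2.51), Il1rn (48.2 and 7.87) and Ptgs2 (7.52 and 0.765). Fxyd4 was at 8.35 FPKM under vehicle and close to 0 under 4-OHT, but its 2 rows together were at 12.7 and 2.01 FPKM.

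Genes higher with 4-OHT in Meis1f/f cells included Amd1, Fscn1, Rbp4 and chemokine genes. Ccr7, the lymph node homing receptor, was at 6.33 FPKM under vehicle and 28.0 under 4-OHT, with 2.30 and 1.74 FPKM in control cells. Fscn1, an actin bundling protein, was at 1.74 and 22.8 FPKM, and the chemokine genes Ccl22 and Ccl5 were at 18.5 and 59.6 FPKM and at 1.06 and 9.84 FPKM. Rbp4, a retinol carrier, was at 1.76 and 21.6 FPKM, Cacnb3 at 0.4 and 5.18 FPKM, Amd1 at 0.505 and 20.5 FPKM and Fam69b at 4.08 and 15.9 FPKM. Amd1 and Fam69b were also higher with 4-OHT in control cells, though short of the size rule. There Amd1 was at 0.661 and 2.13 FPKM (ratio 3.21, interval 2.38 to 4.44). Fam69b was at 5.54 and 9.08 FPKM (ratio 1.64, interval 1.38 to 1.93). Fscn1, Rbp4, Ccl22 and Cacnb3 were not higher in control cells, and Ccl5 was at 1.22 and 1.49 FPKM. Amd1 has near-identical copies in the mouse genome, so its value is uncertain. The dendritic list, which holds Ccr7, was not apart in Meis1f/f cells (14 genes, median 0.14, percentile 54.7, 1 higher and 1 lower). The rows used for Cdk10, Fancg, Rad54l and Bace1 were low in the Meis1f/f vehicle library alone. Fancg was at 8.21, 9.24, 1.33 and 8.07 FPKM in the order of groups above. With their rows summed none of these 4 genes was deletion-associated: the difference of the effects was 0.28 for Cdk10, 0.54 for Fancg, 0.49 for Rad54l and 0.98 for Bace1.

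**Figure D1:**
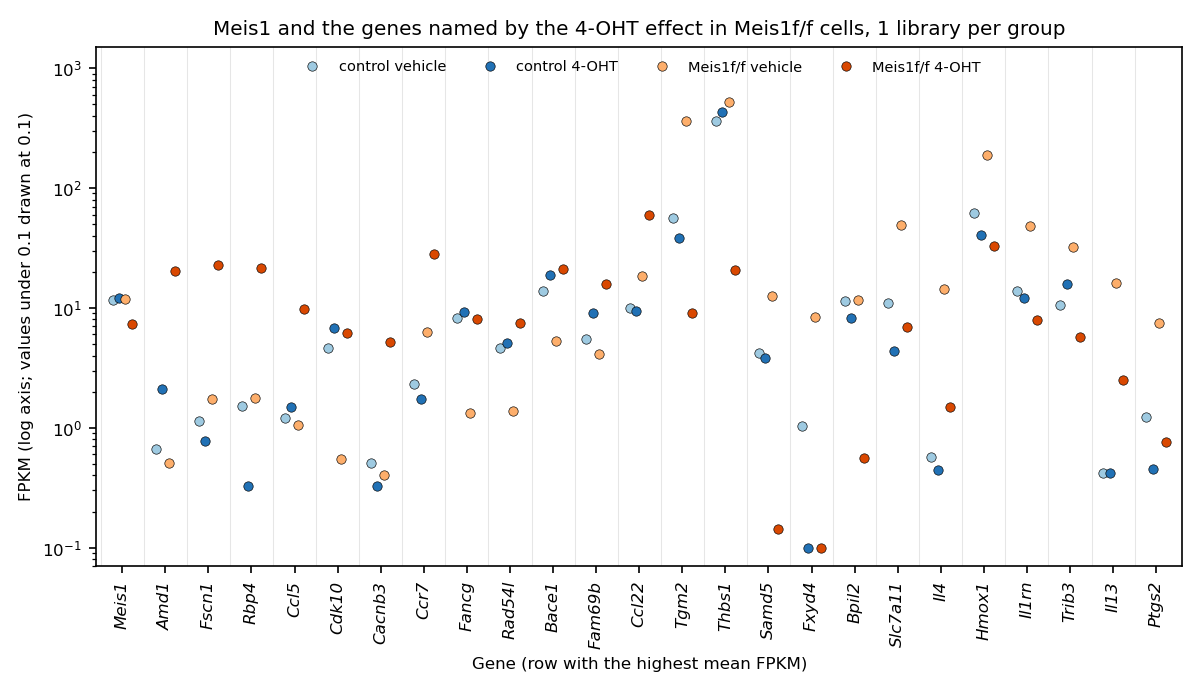
FPKM (log axis) of Meis1 and of the 24 deletion-associated genes named by rule, with 1 point per library and no error bars because each group has 1 library; values under 0.1 are drawn at 0.1. Thbs1 sits between 362 and 521 FPKM in the control vehicle, control 4-OHT and Meis1f/f vehicle libraries and at 20.8 FPKM in Meis1f/f 4-OHT.

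Of 10922 genes, 178 were higher and 249 lower by the size rule with 4-OHT in Meis1f/f cells, and 231 were higher and 396 lower in the difference of the 4-OHT effects. Deletion-associated genes numbered 84 higher and 167 lower, of which 36 and 45 also differed the same way between the 4-OHT libraries, a comparison without the Meis1f/f vehicle library. Thbs1, Tgm2, Samd5, Bpil2, Fscn1, Rbp4 and Ccr7 were among the latter. Hmox1, Slc7a11, Il1rn, Il4 and Ptgs2 were not, since they differed by less than 1 (log2) between the 4-OHT libraries. Both 4-OHT libraries also entered the rule for deletion-associated genes, so passing this comparison was favoured in advance and is no independent check. Of all 10922 genes, 406 were higher and 176 lower in it. The split depended on scaling: median ratio rescaling gave 113 higher and 359 lower in Meis1f/f cells (23.9% higher, against 41.7% as deposited) and 61 and 223 deletion-associated genes. That rescaling shifted the median of all genes in Meis1f/f cells by -0.12 (log2), and upper quartile rescaling gave 124 higher and 317 lower in Meis1f/f cells and 62 and 213 deletion-associated genes.

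Genes of oxidative metabolism were higher with 4-OHT in Meis1f/f cells. The median over 77 nuclear-encoded oxidative phosphorylation genes was 0.39 (log2) in Meis1f/f cells (percentile 100) and -0.10 in control cells (percentile 15.1), and the difference of the effects was 0.44 (percentile 100). No member reached a difference of 1, and the median in Meis1f/f cells was 0.25 under median ratio rescaling and 0.30 under upper quartile rescaling. As deposited, random lists matched on expression centred on 0.17 in Meis1f/f cells and on 0.26 for the difference of the effects. Genes of like expression thus shared part of the shift. Cyc1, cytochrome c1 of complex III, was at 146 and 135 FPKM in control vehicle and 4-OHT and at 81.7 and 144 FPKM in Meis1f/f vehicle and 4-OHT. Uqcr11 was at 145, 125, 85.1 and 141 FPKM, and cytochrome c, Cycs, was at 96.7, 84.3, 53.1 and 81.7 FPKM. The 23 genes of the tricarboxylic acid cycle had a median of 0.38 in Meis1f/f cells (percentile 99.3), among them Idh3a at 70.2, 68.0, 37.6 and 63.6 FPKM; their difference of the effects was 0.38 (percentile 96.8), and the call in Meis1f/f cells was lost when the length trend was removed. Between the 4-OHT libraries the oxidative phosphorylation median was 0.00 (percentile 59.1). Between the vehicle libraries it was -0.44 (percentile 0), where matched random lists centred on -0.26. The Meis1f/f vehicle library also carried a trend with transcript length: Spearman's rho across genes of length with the difference was -0.24 for 4-OHT in Meis1f/f cells, 0.25 between the vehicle libraries and 0.03 between the 4-OHT libraries.

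Replication, chaperone and primary granule genes were higher with 4-OHT in Meis1f/f cells as well. The DNA replication and S phase list (41 genes) had a median of 0.40 (percentile 100.0), with Fen1, the flap endonuclease, at 84.4, 67.2, 39.9 and 59.4 FPKM. Heat shock genes (12) had a median of 0.49 (percentile 99.8), with the chaperone gene Hspa8 at 1388, 1308, 719 and 1377 FPKM. Primary granule genes (14) had a median of 0.63 (percentile 100), among them Gfi1, a repressor needed for granulopoiesis, at 34.6, 37.5, 15.6 and 47.0 FPKM, Ms4a3 at 645, 738, 281 and 685 FPKM and the proteinase 3 gene Prtn3 at 1005, 1275, 505 and 1013 FPKM. Each of these 3 lists was lower in Meis1f/f than control cells under vehicle, with medians of -0.41, -0.70 and -0.56. Between the 4-OHT libraries, which leave out the Meis1f/f vehicle library, none was higher: the medians were -0.14 (percentile 0.01), 0.01 (percentile 55.0) and -0.12 (percentile 1.15). The heat shock call in Meis1f/f cells was lost without the floor. Mitosis genes (39) had a median of 0.23 in Meis1f/f cells and were not apart (percentile 84.8), nor were the 29 mitochondrial biogenesis genes (0.27, percentile 91.6).

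HIF target and hypoxia genes were higher with 4-OHT in control cells, and their median was below 0 in Meis1f/f cells. The median (24 genes) was 0.56 in control cells (percentile 100), with 5 members higher by the size rule. In Meis1f/f cells it was -0.20 (percentile 0.08) with an interval over members from -0.43 to 0.05, 2 members lower by the size rule and 9 above 0; over the alternatives it ran from -0.12 (length trend removed or a pseudocount of 5) to -0.32 (median ratio rescaling). The difference of the effects was -0.74 (percentile 0), with 11 members lower and 0 higher by the size rule. Ndrg1 was at 16.9 and 51.3 FPKM in control vehicle and 4-OHT and at 34.8 and 16.5 FPKM in Meis1f/f vehicle and 4-OHT. Egln3, a HIF prolyl hydroxylase, was at 34.1, 128, 39.3 and 39.6 FPKM, Ankrd37 at 2.56, 12.8, 2.68 and 1.73 FPKM, and Vegfa at 9.65, 23.0, 9.12 and 6.69 FPKM. Hif1a itself was at 71.5, 58.8, 70.6 and 71.6 FPKM. Glycolysis genes (26) had medians of 0.28 in control cells (percentile 100), -0.22 in Meis1f/f cells (percentile 0) and -0.57 for the difference (percentile 0). In Meis1f/f cells the interval over members ran from -0.42 to 0.25 with 11 members above 0, and the median was -0.12 with rows summed and -0.35 under median ratio rescaling. Aldoc was at 32.8, 38.1, 58.9 and 12.7 FPKM, the lactate exporter gene Slc16a3 at 64.3, 163, 34.4 and 28.5 FPKM, the glucose transporter gene Slc2a1 at 35.6, 96.0, 28.6 and 36.9 FPKM, and Pgk1 at 1220, 1111, 945 and 465 FPKM. Both lists were also lower in Meis1f/f than control cells between the 4-OHT libraries, with medians of -0.99 and -0.72.

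With 4-OHT the medians of cholesterol synthesis and integrated stress response genes were also above 0 in control cells and below 0 in Meis1f/f cells. The 25 cholesterol and SREBP2 target genes had medians of 0.26 in control cells (percentile 100) and -0.40 in Meis1f/f cells (percentile 0), a difference of -0.68. In Meis1f/f cells the interval over members ran from -0.82 to 0.10 with 8 members above 0. Hmgcs1, which makes HMG-CoA, was at 28.1, 38.8, 61.1 and 20.0 FPKM. The 17 LXR target and fatty acid genes had a difference of -0.25 (percentile 0.23), with Scd1 at 42.6, 52.9, 46.7 and 19.0 FPKM. The integrated stress and unfolded protein response list (30 genes) had medians of 0.14 in control cells (percentile 99.9) and -0.32 in Meis1f/f cells (percentile 0), a difference of -0.40, with 9 members lower. Its interval over members in Meis1f/f cells ran from -0.68 to 0.05 with 10 members above 0. Unlike the HIF list (-0.01, percentile 80.9), this list was higher in Meis1f/f than control cells under vehicle (0.18, percentile 99.97, 7 members higher). Between the 4-OHT libraries it was at -0.15 (percentile 0.01) with 2 members lower. Within it Asns, asparagine synthetase, was at 53.2, 85.9, 132 and 66.6 FPKM and the amino acid transporter gene Slc7a5 at 94.2, 110, 239 and 99.4 FPKM.

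**Figure D2:**
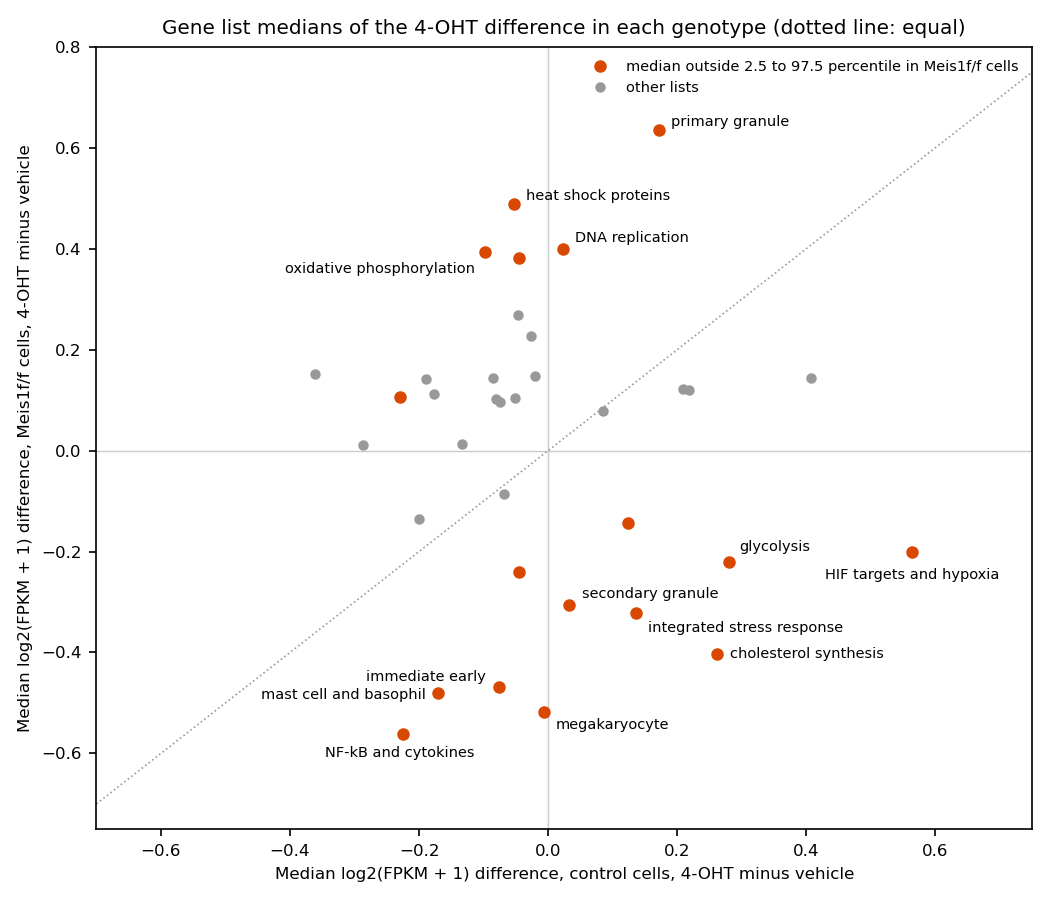
Median log2(FPKM + 1) difference between 4-OHT and vehicle for 35 gene lists, in control cells (x axis) and in Meis1f/f cells (y axis), with lists called apart in Meis1f/f cells in orange. Oxidative phosphorylation lies at -0.10 and 0.39 and the HIF list at 0.56 and -0.20.

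Inflammatory and immediate early genes were lower with 4-OHT in Meis1f/f cells. The 21 NF-kB and cytokine genes had a median of -0.56 (percentile 0), with 6 lower and 1 higher by the size rule; the lower ones included Il1rn, Ptgs2 and the chemokine gene Cxcl2 (4.98 and 1.28 FPKM), and the higher one was Ccl5. In control cells the median was -0.22 (percentile 0.04). The 26 immediate early genes had a median of -0.47 in Meis1f/f cells (percentile 0), with Klf2 at 6.98, 17.8, 11.0 and 5.67 FPKM in the order of groups above. Secondary and tertiary granule genes (22) had a median of -0.30 (percentile 0.01) and none passed the size rule; Retnlg was at 11.3 FPKM under vehicle and 5.19 under 4-OHT. Genes of signalling by the culture cytokines (21) had a median of -0.24 (percentile 0.08), and megakaryocyte genes (11), which include Thbs1, one of -0.52 (percentile 0.04). In the difference of the effects the megakaryocyte list was not apart (-0.33, percentile 3.45). The mast cell and basophil list (15) had a median of -0.48 (percentile 0): Il4, Il13, Hdc (273 and 89.4 FPKM) and Prss34 (232 and 104 FPKM) were lower by the size rule, while Cpa3 was at 355 and 652 FPKM. With rows summed the mast cell median was -0.31. In the difference of the effects the mast cell list was not apart either (-0.04, percentile 19.6), and in control cells its median was -0.17 (percentile 2.37). These lists were higher in Meis1f/f than control cells under vehicle, with genotype medians from 0.33 for the culture cytokine genes to 2.69 for the mast cell genes. Between the 4-OHT libraries, which leave out the Meis1f/f vehicle library, they were higher in Meis1f/f cells too, with medians of 0.28 (NF-kB), 0.29 (immediate early) and 0.55 (secondary granule).

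In control cells, which the labels give no CreER, 4-OHT went with higher levels of HIF targets. The 5 highest genes were Ankrd37 (2.56 to 12.8 FPKM), Egln3 (34.1 to 128), Tcf19 (2.05 to 8.94), Tifab (20.6 to 63.2) and Ndrg1 (16.9 to 51.3). Tifab was also higher in Meis1f/f cells, at 12.2 and 36.5 FPKM. The 5 lowest were Repin1, Slco4a1 (110 to 24.7 FPKM), Tmem176b (6.17 to 0.742), the eosinophil-attracting chemokine gene Ccl24 (10.4 to 2.11) and the beta globin gene Beta-s (83.2 to 25.9). The row used for Repin1 was at 5.47 and 0.0055 FPKM, but its 6 rows together were at 9.01 and 5.69 FPKM; those of Tcf19 were at 9.06 and 13.1 FPKM and those of Tmem176b at 9.50 and 4.73 FPKM. By the size rule 150 genes were higher and 96 lower, but with a pseudocount of 5 the split turned to 13 higher and 20 lower. Among lists, BCL2 family (0.22, percentile 99.5), monocyte (0.21, percentile 100.0), primary granule (0.17, percentile 100.0) and dendritic genes (0.41, percentile 100.0) were higher, with the class II transactivator gene Ciita at 0.751 and 3.06 FPKM. Ribosomal protein (-0.23, percentile 0), erythroid (-0.36, percentile 0), stem and progenitor (-0.19, percentile 0.23), TALE homeobox (-0.29, percentile 1.4) and mast cell genes (-0.17, percentile 2.37) were lower. Of these calls, all but those of the ribosomal protein and erythroid lists were lost under at least 1 alternative.

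Across 10922 genes the differences with 4-OHT in control and Meis1f/f cells, which share no library, had a Pearson correlation of 0.24 and a Spearman correlation of 0.28; genes are not independent replicates. Among the genes past the size rule, 13 were higher in both genotypes, against 2.44 for independent lists of these sizes, and 17 were lower in both, against 2.19. Independence here takes every gene as equally likely to pass the rule, which was not checked. Repin1 was a shared lower gene only through the row used, since its summed rows differed by -0.58 in control and -0.06 in Meis1f/f cells. Tifab was 1 of the shared higher genes, and Slc7a11 1 of the shared lower genes (11.0 and 4.41 FPKM in control cells). Another 7 genes higher in control cells were lower in Meis1f/f cells, Ndrg1 among them, against 3.42 for independent lists, and 4 lower in control cells were higher in Meis1f/f cells, against 1.56.

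Under vehicle, Meis1f/f cells had higher levels of mast cell, basophil and other lineage genes than control cells. Mcpt8, a basophil protease, was at 113 FPKM in control and 1466 in Meis1f/f cells, Hdc, histidine decarboxylase, at 16.9 and 273 FPKM, the chymase gene Cma1 at 3.32 and 43.7 FPKM and Il13 at 0.418 and 16.1 FPKM. Of 15 mast cell and basophil genes, 13 were higher by the size rule (median 2.69, percentile 100), including Cpa3 (54.2 and 355 FPKM) and the transcription factor gene Gata2 (16.9 and 105 FPKM). The stefin genes Stfa2 (23.4 and 420 FPKM), Stfa3 (8.71 and 147) and Stfa2l1 (21.9 and 278) were higher, but they are a family of near-identical copies and their values are uncertain. Il6 was at 4.31 and 86.3 FPKM, Chi3l3 at 259 and 2620 and Pga5 at 1.51 and 24.0. Erythroid genes (median 1.38, 12 of 15 higher, 1 lower) included Gata1 at 2.82 and 19.8 FPKM and Hba-a1 at 2.20 and 15.2 FPKM. Dendritic genes (median 1.08, 8 of 14 higher) included H2-Aa at 52.1 and 138 FPKM, H2-Ab1 at 47.7 and 102 and Itgax at 2.57 and 17.4. Eosinophil (1.10), T and NK cell (1.64), megakaryocyte (0.84), secondary granule (0.79) and monocyte genes (0.24) were higher too, each at a percentile of at least 99.9, although the T and NK cell call was lost without the floor. In the megakaryocyte list, F2r was at 9.43 and 81.9 FPKM.

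HOXA cluster and MLL-fusion programme genes were lower in Meis1f/f than control cells under vehicle (24 genes, median -0.48, percentile 0), with 7 lower and 1 higher by the size rule; the call was lost with a floor of 5 FPKM. Hoxa9 was at 31.3 and 12.2 FPKM and Hoxa7 at 14.5 and 6.13. With 4-OHT this list was not apart in Meis1f/f cells (0.15, percentile 68.8), although Lmo2 was at 24.1 and 68.5 FPKM and Satb1 at 2.41 and 0.658 FPKM. The lowest genes between genotypes included Csn2 (48.0 and 2.72 FPKM), Hebp1 (23.2 and 2.68), Xlr (5.83 and 0.119), Ms4a6c (10.3 and 1.14), Cnn3 (12.1 and 1.68), Mid1 (18.6 and 3.11), Phf17, Tctex1d1 (5.75 and 0.680) and Fancg. The row used for Phf17 was at 5.92 and 0.709 FPKM, but its 4 rows together were at 7.95 and 8.06 FPKM. By the size rule 638 genes were higher and 230 lower in Meis1f/f cells under vehicle, and 406 and 176 under 4-OHT.

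**Figure D3:**
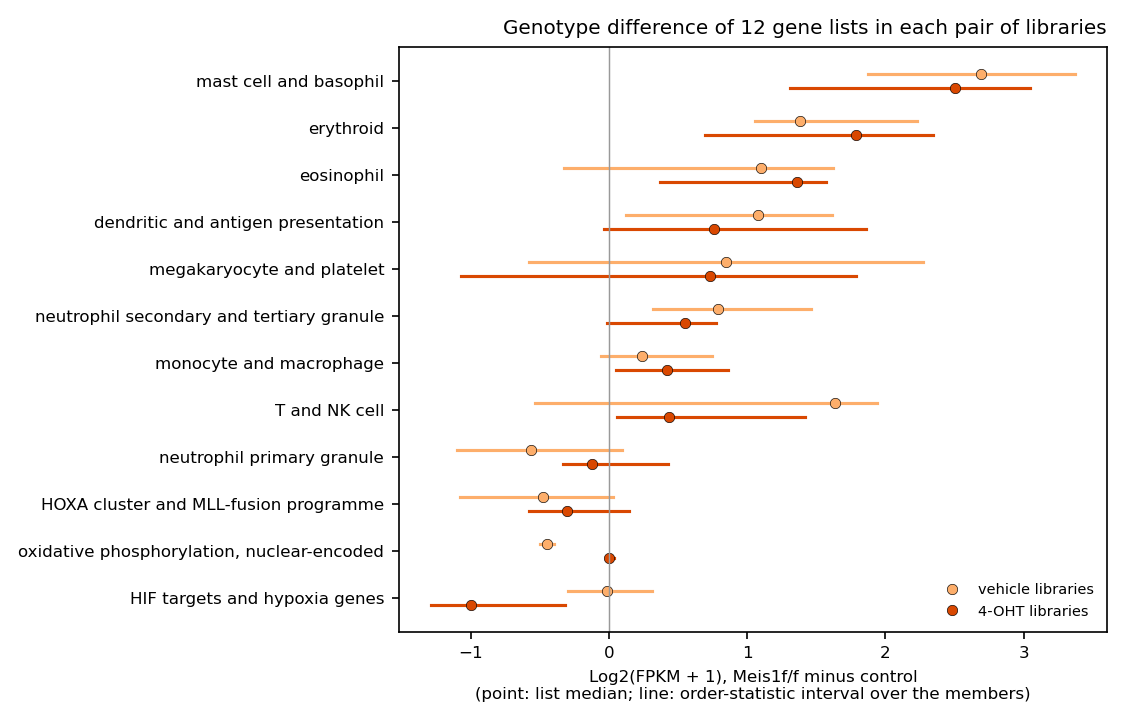
Median difference of log2(FPKM + 1) between Meis1f/f and control cells for 12 gene lists, under vehicle (light points) and under 4-OHT (dark points), with lines for the order-statistic interval over the members, not over replicates. The mast cell and basophil medians are 2.69 and 2.51, oxidative phosphorylation is at -0.44 under vehicle and 0.00 under 4-OHT, and the HIF list is at -0.01 and -0.99.

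In the difference of the 4-OHT effects, p53 targets (31 genes) had a median of 0.04 (percentile 60.4), with Trp53inp1 at 4.49, 1.03, 10.9 and 9.32 FPKM (its rows together at 6.56, 5.0, 17.4 and 11.5), and CDK inhibitor and senescence genes (12) one of 0.00 (percentile 33.2), with Cdkn2a at 2.05, 2.22, 4.42 and 9.78 FPKM. Antioxidant genes (42) had a difference of 0.16 (percentile 20.2), although Hmox1 and Srxn1 (12.5, 13.8, 42.2 and 14.8 FPKM) were lower by the size rule. PAR bZIP and C/EBP genes (8) were at 0.21 (percentile 71.7), with Cebpa at 62.0, 62.2, 41.3 and 55.8 FPKM. Interferon response (-0.07, percentile 57.0), oestrogen-responsive (-0.05, percentile 25.6), ribosomal protein (0.32, percentile 78.1), stromal (0.02, percentile 53.4), T and NK cell (-0.22, percentile 16.8), eosinophil (0.35, percentile 89.3), monocyte (0.12, percentile 24.5) and mast cell genes (-0.04, percentile 19.6) were not apart. BCL2 family genes were lower (-0.31, percentile 0), with no member past the size rule and the call lost with the mean, and so were dendritic genes (-0.31, percentile 0.5), which were at 0.0075 without the floor. Stem and progenitor genes were higher (0.40, percentile 99.9), with 12 of 19 members above 0; Sox4 (8.20, 4.44, 2.81 and 5.50 FPKM) and Cd34 (4.91, 2.01, 9.40 and 11.7 FPKM) were higher by the size rule and Egr1 (0.529, 1.52, 6.15 and 4.27 FPKM) was lower, as Meis1 was by less. Also higher were TALE homeobox genes (0.41, percentile 97.9) and erythroid genes (0.34, percentile 98.9); a pseudocount of 5 ended these 3 calls. The B cell and sex-linked lists had 3 and 4 members over the floor; the Y-linked genes Ddx3y (16.3, 16.5, 21.1 and 18.2 FPKM) and Eif2s3y (34.8, 35.5, 34.8 and 36.7 FPKM) were present in every library.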

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

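The tests below that matched random lists on transcript length, compared the 4-OHT libraries, or took Meis1f/f cells alone were chosen after the data were seen. With 4-OHT 4 gene lists were apart from random lists in opposite directions in control and Meis1f/f cells, and among the named genes 1, Ndrg1, passed the size rule in opposite directions; the difference of the effects was not tested because each group has 1 library. The difference of the effects was -0.74 for HIF targets and -0.57 for glycolysis genes. It was -0.68 for cholesterol synthesis genes and -0.40 for integrated stress response genes. Ndrg1, a hypoxia-induced gene, had a difference of the effects of -2.58.

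HIF target genes were lower in the difference of the 4-OHT effects. A trend with transcript length was argued against, since the median stayed at percentile 0 among random lists matched on length as well. The Meis1f/f vehicle library as the whole cause was argued against by the comparison of the 4-OHT libraries, which leaves it out and where the list was at percentile 0 with a median of -0.99. In Meis1f/f cells alone the list was at percentile 0.08, but it was picked for its sign there. The interval of its median ran from -0.43 to 0.05, so a fall in Meis1f/f cells was not settled. In control cells the median was 0.56, with an interval over members from 0.31 to 0.84 and 23 of 24 members above 0. Under vehicle the genotypes differed by a median of -0.01. The larger part of the difference of the effects thus lay between the control libraries. Whether the control 4-OHT library stands apart or the genotypes respond differently to 4-OHT cannot be told with 1 library per group. Loss of Meis1 and CreER activation may contribute and stay untested.

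The 4 members that glycolysis and HIF lists share did not carry the glycolysis value. Without them the 22 remaining glycolysis genes had medians of 0.28 in control cells and -0.34 in Meis1f/f cells, and the 20 remaining HIF genes had 0.62 and -0.27.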

How the results depend on the processing

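No paired analysis was run, and with 1 library per group no library could be left out within a group. Across 13 alternatives, between 82 and 98 list calls kept their direction, 1 to 17 were lost and 0 turned. Removal of the length trend, transcripts of every status and random lists matched on length or GC content were chosen after the data were seen, as were the genotype comparison under 4-OHT and the count of genes also apart between the 4-OHT libraries.

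With a pseudocount of 0.1, higher and lower genes numbered 479 and 203 for 4-OHT in control cells, 423 and 433 in Meis1f/f cells, 430 and 718 for the difference of the effects, 1052 and 398 between genotypes under vehicle and 646 and 338 under 4-OHT. Deletion-associated genes numbered 183 and 285, of which 71 and 105 were also apart between the 4-OHT libraries. With a pseudocount of 5 the same counts were 13 and 20, 38 and 72, 53 and 109, 237 and 55, 150 and 51, then 16 and 45, and 10 and 11, and the Meis1 difference in Meis1f/f cells was -0.44. A larger pseudocount shrinks each log2 difference of a gene between a pair of libraries by construction, most of all for low genes. A difference of the effects need not shrink.

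With a floor of 5 FPKM, which leaves fewer genes, 92 genes were higher in control cells, 242 were lower in the difference of the effects, and 262 and 106 differed between genotypes under 4-OHT. Deletion-associated genes were then 50 and 100, with 15 and 27 also apart between the 4-OHT libraries. The interferon median between genotypes under vehicle reversed to -0.41 with that floor, and the dendritic median for the difference of the effects reversed to 0.0075 with no floor.

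Median ratio rescaling gave 113 higher genes in Meis1f/f cells, an oxidative phosphorylation median of 0.35 for the difference of the effects, and a reversed ribosomal protein median in Meis1f/f cells of -0.0366. Upper quartile rescaling gave an oxidative phosphorylation median of 0.35 (0.3467). Removing the length trend gave 0.26 for it and reversed the ribosomal protein median in Meis1f/f cells to -0.0173. Summing the rows of a symbol gave 63 lower genes in control cells and a Meis1 difference of -0.86. It reversed Phf17 between genotypes under vehicle (0.0184), and Trp53inp1 (-0.22) and Stat5a (-0.35) in the difference of the effects. The mean in place of the median reversed the antioxidant value between genotypes under 4-OHT to -0.0165. Except for the pseudocount and the floor, the cause was not tested.

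On reads simulated at the estimated depths, 11 of 10351 unchanged genes passed the size rule in Meis1f/f cells through counting noise. Of these, 1 was among the 7455 genes of at least 5 FPKM. For the difference of the effects 35 passed. The simulation held no variation between cultures and no splitting of reads between transcripts, so these counts do not give the rate of false calls in the data.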

Other observations

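The tests of oxidative phosphorylation genes with lists matched on length or GC content or between the 4-OHT libraries, and both tests of mast cell genes, were chosen after the data were seen. P53 target genes were higher in Meis1f/f than control cells under vehicle (31 genes, median 0.37, percentile 99.96) and under 4-OHT (0.19, percentile 99.96), with 5 and 7 members higher by the size rule and 0 lower. The interval over members ran from 0.12 to 0.61 under vehicle, with 24 members above 0 and 7 below. Under 4-OHT it ran from -0.05 to 0.43, with 18 above 0 and 13 below. Perp, a desmosomal protein gene, was at 7.54 FPKM in control vehicle, 6.21 in control 4-OHT, 43.2 in Meis1f/f vehicle and 30.9 in Meis1f/f 4-OHT cells. Phlda3, an inhibitor of AKT, was at 1.42, 1.84, 4.47 and 8.11 FPKM, and Zmat3 at 2.27, 1.86, 6.11 and 6.65 FPKM. The CDK inhibitor gene Cdkn2b was at 0.954, 0.507, 13.1 and 7.11 FPKM. Its list, CDK inhibitor and senescence genes, was not apart between genotypes under vehicle (0.16, percentile 91.1) or 4-OHT (0.07, percentile 81.4).

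Receptor and signalling genes of the cytokines in the medium were higher in Meis1f/f than control cells (21 genes, median 0.33 under vehicle and 0.40 under 4-OHT, or 0.14 under 4-OHT with rows summed), with 4 and 5 members past the size rule. Csf2rb, the shared beta chain of the GM-CSF and IL-3 receptors, was at 101, 97.8, 242 and 205 FPKM. Its paralog Csf2rb2, which serves IL-3 and is close to it in sequence, so that reads can be shared, was at 28.4, 30.2, 159 and 126 FPKM. Osm, the oncostatin M gene, was at 7.03, 8.46, 32.6 and 24.6 FPKM.

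Oxidative phosphorylation genes were higher in the difference of the 4-OHT effects. Length was argued against as the whole cause by a percentile of 99.68 among lists matched on it, and GC content by a percentile of 100. Removing the length trend lowered the median to 0.26, so length may account for part. The list was at percentile 59.14 between the 4-OHT libraries, as it would be if the Meis1f/f vehicle library alone stood apart, and that library was also the only one in its lane. A technical difference of that library and a response to 4-OHT in Meis1f/f cells therefore both stay open.

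Il4, Il13, Hdc and Prss34 were lower with 4-OHT in Meis1f/f cells. A smaller share of both mast cells and basophils would lower the whole list. The median over its 15 members was -0.4805 with an interval over members from -1.15 to 0.37, which leaves that open. The list pools both cell types, so its median cannot test a smaller share of either alone. Of the members 10 were below 0, but 5 were above 0, Cpa3 among them. The 4 genes were still higher in Meis1f/f than control cells under 4-OHT, with a median of 1.68 but a range from 0.80 to 2.51, so a Meis1f/f vehicle library that stands apart and a response to 4-OHT cannot be told apart for them. Of the list's members, 2 are in another list and 12 were at 1 FPKM or more in both control libraries.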
